A study of Mus musculus with 12 samples.

How the data were processed

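The series measured RNA in RAW 264.7 cells, a mouse macrophage line, by sequencing of bulk libraries. Per the labels' protocols, cells were nucleofected with a short hairpin RNA (shRNA) against PHLPP1 or against luciferase (sh-Luc, the control) and selected with puromycin as 1 stable line each. Each line was left untreated or given oxidised low-density lipoprotein (OxLDL) at 100 µg/ml for 24 h. This made 4 groups of 3 libraries, and the labels number the libraries of each group 1, 2 and 3 for culture passages 9, 10 and 11. The p-values given here therefore measure the spread between cultures of a line at successive passages, not the spread between independently made lines. In the main fit this spread was pooled over the 4 groups, also where only 2 groups were compared. Because the untreated libraries labelled sh-PHLPP1 did not hold fewer transcripts of the targeted gene, these libraries are called by their label throughout.

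The count table deposited by the authors holds raw read counts (whole numbers, 39179 Ensembl genes by 12 libraries), and every one of its 12 columns was used. Per the submitters' processing notes, FastQC, Trimmomatic, HTSeq and DESeq2 were used with mouse build GRCm38, without versions. The aligner, the strand setting and the annotation release were not given in the sources used here. The labels' protocols describe libraries made from total RNA with a commercial RNA kit, and the submitters state that the raw reads were lost. The authors also deposited tables for 3 comparisons with log2 fold changes (log2 ratios of the group means, from DESeq2) and an adjusted p-value per gene. These tables served only for a comparison of calls. Totals ran from 16020186 to 27422114 counts per library. A gene at 0 in a library could have had up to 3 counts there, which corresponds to 0.109 to 0.187 CPM (the count scaled to a common library total) and to 0.0999 to 0.222 CPM on the TMM scale. Such limits and the intervals by counting cover counting error only, since reads copied by PCR are not independent molecules. The interval of a fold change comes from the edgeR fit and includes the spread between replicates. No row for the 37 mitochondrially encoded genes held any count, so RNA quality was not judged from them. Rows without a gene symbol (1632) held 0.397 to 0.505% of the counts. Gene positions came from GENCODE M21 (GRCm38), which contained 37607 of the gene identifiers, 37172 of them with the symbol of the table. Symbols shared by more than 1 row (150) were kept as separate rows.

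Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low counts were removed with filterByExpr, which left 13121 genes, and libraries were scaled with TMM factors. The quasi-likelihood test was fitted to the 4 group means over all 12 libraries, with no block for replicate number. The common biological coefficient of variation was 0.171. Benjamini-Hochberg adjustment ran over all genes tested and a gene was called at an adjusted p under 0.05. All edgeR tests were 2-sided. Comparisons were OxLDL against untreated in each line, the libraries labelled sh-PHLPP1 against sh-Luc in each treatment, and the interaction, which is the OxLDL response of the sh-PHLPP1 line minus that of the sh-Luc line. Levels are given as CPM on the TMM scale, mean ± SD of the 3 libraries of a group. Fold changes carry a standard error (SE) on the log2 scale. It was taken as the size of the log2 fold change over the square root of the F statistic of its test. This SE is approximate, and the 95% intervals of fold changes were built on it.

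Genes named in the text followed a rule set before the data were examined. For each comparison of 2 groups it took up to 8 genes with the highest and 8 with the lowest log2 fold change among called genes, with an average log2 CPM of at least 2 and no overlap between the groups' values. For the interaction it took up to 5 in each direction. Predicted genes and genes without a symbol were left out. A member of a gene list was named only if it was among the 3 with the smallest p of that list in that comparison. Phlpp1, Phlpp2, Mlxipl, Prkaa1, Prkaa2, Srebf1, Acaca, Fasn and Cd36 could be named everywhere. Results for a few list members that met the rule are not reported here. Of 58 named genes checked for annotated neighbours, 5 overlapped another gene with at least 5% of their own count, namely Srebf1 with Rai1, Avil with Tsfm, Kif20a with Cdc23, Ccne2 with Ints8, and Gbp8 with Gbp9, the last on the same strand. Counts of Cstdc4, Apol9b, Gbp8 and Pirb, which have close relatives in the genome, are less certain.

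In all, 22 gene lists were also fixed before the data were examined. They covered cholesterol synthesis, fatty acid and triglyceride synthesis, lipoprotein and fatty acid uptake, cholesterol efflux and LXR targets, fatty acid oxidation and PPAR targets, lipid droplets and lipolysis, and glycolysis. Others covered AMPK, AKT and PHLPP signalling, NRF2 and oxidative stress, inflammatory cytokines and NF-kB targets, the type I interferon response, endoplasmic reticulum and integrated stress, lysosome and autophagy, and the cell cycle. The remaining lists held markers of macrophage identity, alternative activation and foam cells, p53 targets and apoptosis, osteoclasts, dendritic cells, lymphocytes, fibroblasts and epithelia, and mitochondrially encoded mRNAs. Lists with at least 3 tested members (19) were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. An estimated correlation served as the alternative.

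The numbers of the libraries were tested as pairs before any block was considered. Correlations across genes between the residuals of same-numbered libraries of different groups ran from -0.278 to 0.277 over 18 pairs, with 5 over 0.1, and 4 of 12 libraries correlated best with their own number. The numbers were therefore not used as pairs. Alternatives were DESeq2 1.42.0 in place of edgeR, its size factors in place of TMM, no filter, only the libraries compared, a replicate block, a log2 fold change of at least 1, and each library left out in turn. Scaling by library size alone, and leaving out both libraries that stand apart from their groups, were added after the data were seen. The steps were tested on simulated data with 200 changed genes before use. Figures were drawn with matplotlib.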

Results

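The series compared RAW 264.7 macrophages of a control line (sh-Luc) with a line labelled sh-PHLPP1, each untreated or after 24 h with OxLDL, a modified lipoprotein that macrophages take up. Its title concerns PHLPP1, a phosphatase acting on AKT and other kinases, and asks about lipid uptake and fatty acid synthesis through AMPK and ChREBP (encoded by Mlxipl). Libraries held 16020186 to 27422114 counts, and Spp1 (osteopontin) was the gene with the most counts in each, with 1.13 to 6.36% of the total. Libraries of a group correlated at 0.966 to 0.995 across genes in log2 CPM. In both untreated groups 1 library stood apart, and these are the libraries left out together below. Replicate 1 of the untreated sh-PHLPP1 group correlated at 0.967 and 0.966 with replicates 2 and 3, which correlated at 0.995 with each other. Replicate 2 of the untreated sh-Luc group correlated at 0.983 and 0.984 with replicates 1 and 3, which correlated at 0.994. In the OxLDL group labelled sh-PHLPP1, replicate 3 correlated at 0.984 and 0.987 with replicates 1 and 2, which correlated at 0.993. That library was left out by itself and not with the others, which gave 6303 genes called between the lines after OxLDL, 6151 for OxLDL in its line and 2397 in the interaction.

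**Figure D1:**
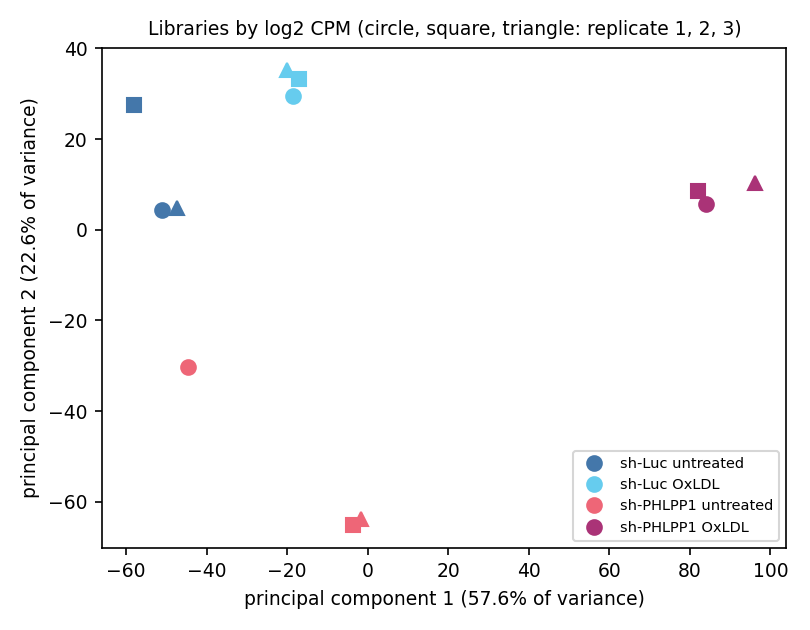
The first 2 principal components of log2 CPM over the tested genes, which hold 57.6% and 22.6% of the variance, with 1 point per library coloured by group and shaped by replicate. Replicate 1 of the untreated sh-PHLPP1 libraries (component 1, -44.6) lies apart from replicates 2 and 3 (-3.64 and -1.64).

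Phlpp1, the targeted gene (ENSMUSG00000044340, chromosome 1, 106171752 to 106394250, GRCm38), was not lower in the untreated libraries labelled sh-PHLPP1. Its level was 12.4, 14.4 and 13.3 CPM in the untreated sh-Luc libraries 1, 2 and 3, and 17.3, 14.6 and 14.0 CPM in the untreated libraries labelled sh-PHLPP1. These levels differed by less than the test could call (log2 fold change 0.19 ± 0.13, SE, adjusted p = 0.279). After OxLDL, Phlpp1 stood at 11.4, 13.5 and 11.4 CPM in sh-Luc and at 8.65, 8.35 and 7.40 CPM in the libraries labelled sh-PHLPP1, where it was lower (-0.57 ± 0.14, adjusted p = 0.00385). A difference of this size was not particular to the targeted gene, since 3619 of 13121 genes were called lower in that comparison. The AMPK, AKT and PHLPP list, which holds Phlpp1, had a median of -0.56 there, with 2 members higher and 15 lower of 24. OxLDL lowered Phlpp1 in the line labelled sh-PHLPP1 (-0.91 ± 0.14, adjusted p = 0.000153), while its change in sh-Luc was not called (-0.14 ± 0.13, adjusted p = 0.534). The data used here held no values for PHLPP1 protein.

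**Figure D2:**
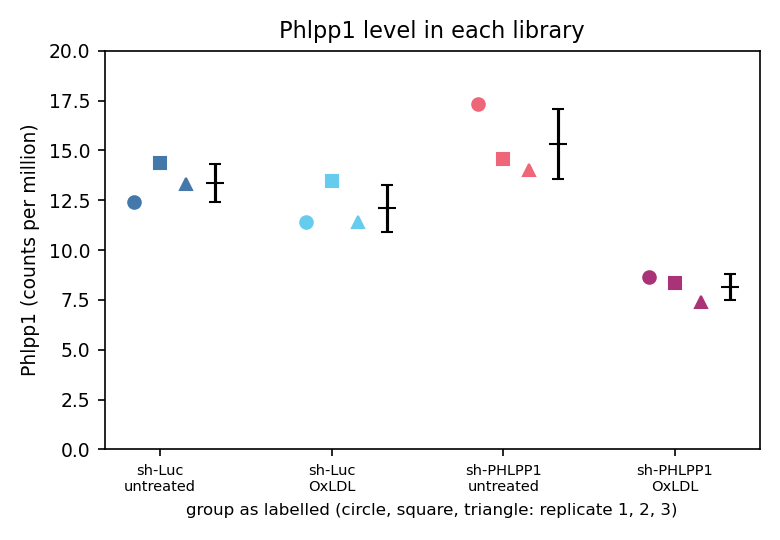
Phlpp1 in CPM (vertical axis, from 0) in each library by group, with circle, square and triangle for replicates 1, 2 and 3, and the mean with its SD in black. The OxLDL-treated libraries labelled sh-PHLPP1 (8.14 ± 0.652 CPM) lie below every other group, and the untreated libraries of that label (15.3 ± 1.76 CPM) do not lie below untreated sh-Luc (13.4 ± 0.974 CPM).

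Other genes of the series title were followed in the same way. Mlxipl had 2 counts over all 12 libraries and Prkaa2, the AMPK alpha 2 subunit, was listed at 0, where up to 3 counts per library could have gone unseen, so neither was tested. Prkaa1, the AMPK alpha 1 subunit, was not called in any of the comparisons of groups, with log2 fold changes of -0.10 and -0.10 for OxLDL in sh-Luc and in the line labelled sh-PHLPP1, and -0.05 and -0.04 between the lines without and with OxLDL. Library size alone, which moved the median of all genes, called it lower between the lines after OxLDL and for OxLDL in the line labelled sh-PHLPP1. Phlpp2, the other member of the phosphatase family, fell with OxLDL in the line labelled sh-PHLPP1 (-0.84 ± 0.19, adjusted p = 0.00246) and was not called in sh-Luc (0.02, adjusted p = 0.951). After OxLDL it was lower in the libraries labelled sh-PHLPP1 (-0.54 ± 0.19, adjusted p = 0.0276), a call lost without sh-Luc OxLDL replicate 1 (-0.46) or sh-PHLPP1 OxLDL replicate 3 (-0.36).

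In sh-Luc cells, OxLDL raised genes of inflammatory signalling and of the oxidative stress response, and lowered interferon-induced genes. The first pair of list calls held with an estimated correlation (adjusted p = 0.0256 and 0.0269) and the interferon call did not (adjusted p = 0.0611). Csf3, which encodes the granulocyte colony-stimulating factor, rose 30.8-fold, from 15.7 ± 8.15 to 484 ± 45.1 CPM (SD, n = 3; log2 fold change 4.94 ± 0.33, SE, adjusted p = 4.75e-06). The chemokine genes Ccl7 (log2 fold change 4.86 ± 0.44), Ccl2 (3.86 ± 0.26) and Cxcl2 (3.68 ± 0.27) rose as well, as did Nos2, the inducible nitric oxide synthase (2.89 ± 0.16, adjusted p = 2.23e-06), and Pdpn (3.09 ± 0.27). Genes that fell included Htr1b, a serotonin receptor (-2.66 ± 0.27), Kbtbd11 (-2.22 ± 0.15), and the interferon-induced Ifi44l (-2.60 ± 0.32) and Ifit3 (-2.16 ± 0.32).

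Of the inflammatory cytokines and NF-kB targets, 12 of 26 members rose, 1 fell and 13 did not pass, with 16 and 1 adjusted over the list alone. The list rose as a whole (camera adjusted p = 5.48e-23 and adjusted p = 0.0256 with an estimated correlation). NRF2 and oxidative stress genes rose too (camera adjusted p = 1.05e-22 and adjusted p = 0.0269 with an estimated correlation). 18 of 25 NRF2 and oxidative stress genes rose, 1 fell and 6 did not pass (19 and 1 adjusted over the list alone). They included Blvrb, the biliverdin reductase (2.02 ± 0.15), Cat, the catalase (1.79 ± 0.13), and Prdx1 (1.48 ± 0.13). Interferon response genes fell as a list (camera adjusted p = 1.01e-34 and adjusted p = 0.0611 with an estimated correlation), and 0 of 32 members rose, 24 fell and 8 did not pass, with 0 and 31 adjusted over the list alone. Examples were Ifit1 (-1.72 ± 0.19) and Ifi44 (-2.11 ± 0.26). The interferon level of untreated sh-Luc replicate 2 (mean log2 CPM of the members) lay below that of replicates 1 and 3, at 6.28, 5.36 and 6.33 in order, and its NRF2 level lay above them, at 6.98, 7.44 and 7.03.

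Genes of lipid droplets rose in sh-Luc cells with OxLDL (camera adjusted p = 4.01e-05 and adjusted p = 0.0553 with an estimated correlation). 3 of 11 lipid droplet genes rose, 1 fell and 7 did not pass (4 and 1 adjusted over the list alone). Plin2, which coats lipid droplets, rose 4.40-fold (2.14 ± 0.14, adjusted p = 4.75e-06) and Hilpda rose 4.73-fold (2.24 ± 0.19). Of the uptake genes, 4 of 16 members rose, 1 fell and 11 did not pass, with 5 and 1 adjusted over the list alone. The list itself missed the threshold (camera adjusted p = 0.05003), which it passed without untreated sh-Luc replicate 2 (adjusted p = 0.000987) or sh-Luc OxLDL replicate 1 (adjusted p = 0.0170), without both libraries that stand apart (adjusted p = 0.00151), with no filter, with DESeq2 size factors or with library size alone. Fabp4, a fatty acid binding protein, rose (2.59 ± 0.24), Stab1, a scavenger receptor, rose (2.22 ± 0.29), and Cxcl16, a chemokine that also binds oxidised lipoprotein, fell (-1.28 ± 0.12). Cd36, a scavenger receptor and fatty acid transporter, rose from 187 ± 82.4 to 419.6 ± 38.6 CPM (1.16 ± 0.24, adjusted p = 0.0104). Fasn, the fatty acid synthase, was not called (-0.78 ± 0.29, adjusted p = 0.115), nor with DESeq2. The authors' table called it lower (-0.78, adjusted p = 4.30e-06), as did the fit of only the 6 libraries compared and the fit without both libraries that stand apart (-0.62, adjusted p = 0.00194). Acaca, the acetyl-CoA carboxylase, fell (-0.57 ± 0.15, adjusted p = 0.0282), a call lost when any library other than untreated sh-Luc replicate 2 was left out (-0.62 to -0.52). The list of fatty acid and triglyceride synthesis was not called (camera adjusted p = 0.598). 2 of 19 fatty acid and triglyceride synthesis genes rose, 1 fell and 16 did not pass (2 and 1 adjusted over the list alone). Cholesterol synthesis fell as a list (camera adjusted p = 0.0441 and adjusted p = 0.750 with an estimated correlation), and this was lost without untreated sh-Luc replicate 1 (adjusted p = 0.0677) or 2 (0.0503) or sh-Luc OxLDL replicate 1 (0.0812). 0 of 24 cholesterol synthesis genes rose, 1 fell and 23 did not pass (0 and 1 adjusted over the list alone).

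Lysosome and autophagy genes rose in sh-Luc cells with OxLDL (camera adjusted p = 6.30e-07 and adjusted p = 0.266 with an estimated correlation), among them Sqstm1, an autophagy receptor (1.49 ± 0.19), Neu1 (0.74 ± 0.11) and the proton pump subunit Atp6v0d1 (0.79 ± 0.15). 10 of 26 lysosome and autophagy genes rose, 1 fell and 15 did not pass (14 and 1 adjusted over the list alone). Untreated sh-Luc replicate 2 already stood higher in this list (7.96, 8.57 and 7.98 for replicates 1, 2 and 3). Alternative activation and foam cell genes rose as a list (camera adjusted p = 0.0165 and adjusted p = 0.0991 with an estimated correlation). 3 of 13 alternative activation and foam cell genes rose, 0 fell and 10 did not pass (6 and 0 adjusted over the list alone). Stress genes of the endoplasmic reticulum (camera adjusted p = 0.0253 and adjusted p = 0.654 with an estimated correlation) rose, with Ppp1r15a (1.33 ± 0.15) and Atf3 (2.16 ± 0.41) as examples, but not without untreated sh-Luc replicate 2 (adjusted p = 0.710), sh-Luc OxLDL replicate 2 (0.0557) or both libraries that stand apart (0.382). 4 of 22 endoplasmic reticulum and integrated stress genes rose, 1 fell and 17 did not pass (4 and 1 adjusted over the list alone). That untreated library stood lower in the list (7.40, 6.41 and 7.48). Glycolysis genes (camera adjusted p = 0.0315 and adjusted p = 0.266 with an estimated correlation) rose, with Hk3 at 1.47 ± 0.15, a list call lost without untreated sh-Luc replicate 2 (adjusted p = 0.0503), sh-Luc OxLDL replicate 2 (0.0961) or both libraries that stand apart (0.0728). 2 of 18 glycolysis genes rose, 0 fell and 16 did not pass (2 and 0 adjusted over the list alone). No cell cycle gene was called by edgeR or by DESeq2 (0 of 30, also adjusted over the list alone and 0 at an unadjusted p under 0.05), although the list lay lower as a whole (camera adjusted p = 0.00650 and adjusted p = 0.750 with an estimated correlation), with a median of -0.44. Without untreated sh-Luc replicate 2 the median was -0.39 and the call was lost (adjusted p = 0.0503), while without both libraries that stand apart the list was called (-0.39, adjusted p = 2.41e-07). Osteoclast markers, which RAW 264.7 cells can express, gave no list call (camera adjusted p = 0.598), but passed when untreated sh-Luc replicate 2 was left out (adjusted p = 0.00597) or both libraries that stand apart (0.00393), and that untreated library stood higher in them (4.32, 5.54 and 4.35). 3 of 14 osteoclast markers rose, 3 fell and 8 did not pass (3 and 4 adjusted over the list alone).

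Lists not called in this comparison were cholesterol efflux and LXR targets (camera adjusted p = 0.971), fatty acid oxidation and PPAR targets (camera adjusted p = 0.971), and AMPK, AKT and PHLPP signalling (camera adjusted p = 0.314). 1 of 17 efflux and LXR target genes rose, 0 fell and 16 did not pass (0 and 0 adjusted over the list alone). 2 of 18 fatty acid oxidation and PPAR target genes rose, 1 fell and 15 did not pass (2 and 1 adjusted over the list alone). 0 of 24 AMPK, AKT and PHLPP signalling genes rose, 1 fell and 23 did not pass (0 and 0 adjusted over the list alone). Macrophage identity (camera adjusted p = 0.658), p53 targets and apoptosis (camera adjusted p = 0.339), and fibroblast and epithelial markers (0 at an unadjusted p under 0.05 with edgeR and 0 called by DESeq2; camera adjusted p = 0.971) were not called either. 2 of 19 macrophage identity genes rose, 3 fell and 14 did not pass (4 and 3 adjusted over the list alone). 4 of 19 p53 target and apoptosis genes rose, 1 fell and 14 did not pass (6 and 2 adjusted over the list alone). 0 of 3 fibroblast and epithelial markers rose, 0 fell and 3 did not pass (0 and 0 adjusted over the list alone). In total 1242 of 13121 genes were called, 837 up and 405 down, 491 of them with a log2 fold change of at least 1 in size. The authors' deposited table called 3060 genes, of which 1184 were called here too, all with the same sign. The count fell to between 564 and 698 when a library other than untreated sh-Luc replicate 2 was left out, with 639 and 697 without untreated replicates 1 and 3, and 698, 564 and 652 without OxLDL replicates 1, 2 and 3. It rose to 3528 without both libraries that stand apart, to 2944 with only the 6 libraries compared, and to 1948 with DESeq2.

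Between the untreated lines, genes of lipid uptake, cholesterol synthesis, inflammation and the osteoclast programme were lower in the libraries labelled sh-PHLPP1, in which Phlpp1 itself was not lower. With an estimated correlation none of these 4 list calls held (adjusted p = 0.188, 0.462, 0.188 and 0.544 in this order), and 5 of 16 uptake genes were called lower. Fabp4 was 40.0-fold lower (0.401 ± 0.0394 against 16.3 ± 5.47 CPM, SD, n = 3; -5.32 ± 0.34, SE, adjusted p = 2.07e-06). Plxna4, a semaphorin receptor (-6.44 ± 0.47), Pdpn (-5.75 ± 0.34) and Uchl1, a deubiquitinase (-4.96 ± 0.30), were also lower, and so was Ctsk, the cathepsin of osteoclasts (-6.34 ± 0.59, adjusted p = 2.76e-05), whose sh-Luc level varied widely (84.1 ± 74.3 CPM). Higher in the libraries labelled sh-PHLPP1 were Cox6a2, a subunit of cytochrome oxidase (6.93 ± 1.04; 24.7 ± 19.8 CPM), Spn, the sialophorin CD43 (4.95 ± 0.68), Parp8 (4.81 ± 0.58) and Chst7 (4.03 ± 0.48).

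Cd36 was 8.70-fold lower in the untreated libraries labelled sh-PHLPP1 (21.5 ± 4.48 CPM; -3.12 ± 0.26, adjusted p = 1.37e-05). Fabp5 was lower too (-2.99 ± 0.44), and the uptake list was lower as a whole (camera adjusted p = 6.95e-06 and adjusted p = 0.188 with an estimated correlation). 0 of 16 uptake genes were higher, 5 were lower and 11 did not pass (0 and 6 adjusted over the list alone). Cholesterol synthesis genes were lower (camera adjusted p = 1.58e-08 and adjusted p = 0.462 with an estimated correlation), for example Hsd17b7 (-0.88 ± 0.14). 0 of 24 cholesterol synthesis genes were higher, 16 were lower and 8 did not pass (0 and 19 adjusted over the list alone). Replicate 1 of the untreated sh-PHLPP1 libraries stood above replicates 2 and 3 in this list, with mean log2 CPM of 6.05, 5.19 and 5.16 against 6.32, 6.30 and 6.28 in untreated sh-Luc. Fatty acid and triglyceride synthesis genes were lower as a list (camera adjusted p = 0.0307 and adjusted p = 0.544 with an estimated correlation), and the same library stood highest (5.84, 5.37 and 5.39). 1 of 19 fatty acid and triglyceride synthesis genes was higher, 5 were lower and 13 did not pass (1 and 5 adjusted over the list alone). This list call was lost without untreated sh-Luc replicate 1 (adjusted p = 0.0945) or 3 (0.0673) or sh-PHLPP1 replicate 2 (0.0742) or 3 (0.0605). Elovl6 (-1.19 ± 0.14), Acaca (-0.68 ± 0.15) and Fasn (-1.31 ± 0.30, adjusted p = 0.00867) were lower. Srebf1, the regulator of lipid synthesis SREBP1, was not called (-0.52, adjusted p = 0.332), except without sh-PHLPP1 untreated replicate 1 (-1.34).

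Inflammatory genes were lower in the untreated libraries labelled sh-PHLPP1 (camera adjusted p = 1.52e-09 and adjusted p = 0.188 with an estimated correlation), among them Nos2 (-3.43 ± 0.17), Ccl2 (-3.39 ± 0.29) and Ptgs2 (-2.65 ± 0.43; -1.74 without untreated sh-Luc replicate 2). 2 of 26 inflammatory genes were higher, 14 were lower and 10 did not pass (2 and 16 adjusted over the list alone). Osteoclast markers were lower (camera adjusted p = 5.37e-05 and adjusted p = 0.544 with an estimated correlation), with Mmp9 at -1.52 ± 0.22, and untreated sh-Luc replicate 2 stood highest in them. 0 of 14 osteoclast markers were higher, 8 were lower and 6 did not pass (0 and 9 adjusted over the list alone). Cell cycle genes were lower as a list (camera adjusted p = 1.52e-09 and adjusted p = 0.544 with an estimated correlation), with Ccne1, cyclin E1, at -1.003 ± 0.14. 0 of 30 cell cycle genes were higher, 14 were lower and 16 did not pass (0 and 24 adjusted over the list alone). Their mean log2 CPM was 7.16, 7.33 and 7.11 in untreated sh-Luc and 7.07, 5.50 and 5.47 in the libraries labelled sh-PHLPP1, where replicate 1 stood near sh-Luc. Glycolysis genes were lower (camera adjusted p = 0.0119 and adjusted p = 0.311 with an estimated correlation), with Slc16a3, a lactate transporter, at -1.11 ± 0.17 and Ldha at -0.60 ± 0.11, a list call lost without sh-PHLPP1 untreated replicate 1 (adjusted p = 0.108) or both libraries that stand apart (0.0947). 0 of 18 glycolysis genes were higher, 8 were lower and 10 did not pass (1 and 8 adjusted over the list alone). The NRF2 list was lower (camera adjusted p = 0.0184 and adjusted p = 0.630 with an estimated correlation), but not without that library (adjusted p = 0.0556), untreated sh-Luc replicate 2 (0.171) or both (0.153). 1 of 25 NRF2 and oxidative stress genes was higher, 7 were lower and 17 did not pass (1 and 9 adjusted over the list alone). The interferon list was not called (camera adjusted p = 0.870), but passed without untreated sh-Luc replicate 2 (adjusted p = 0.00164). 3 of 32 interferon response genes were higher, 4 were lower and 25 did not pass (2 and 4 adjusted over the list alone).

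Other lists did not pass between the untreated lines. Cholesterol efflux and LXR targets (camera adjusted p = 0.852) went both ways, with a median of -0.05 and a mean of 0.11, and Smpdl3a was higher (2.28 ± 0.40). 4 of 17 efflux and LXR target genes were higher, 1 was lower and 12 did not pass (4 and 1 adjusted over the list alone). Alternative activation and foam cell genes (camera adjusted p = 0.852) had a median of -0.25 and a mean of 0.16, with Klf4 higher (2.37 ± 0.22). 2 of 13 alternative activation and foam cell genes were higher, 1 was lower and 10 did not pass (3 and 2 adjusted over the list alone). Of the AMPK, AKT and PHLPP list, Fkbp5 was lower (-0.60 ± 0.12; 3 up and 2 down of 24, 3 and 2 adjusted over the list alone; camera adjusted p = 0.935). Stress genes Ddit3 (2.26 ± 0.34) and Ppp1r15a (1.17 ± 0.15) were higher and Creld2 lower (-0.997 ± 0.17) in a list that was not called (camera adjusted p = 0.686). 6 of 22 endoplasmic reticulum and integrated stress genes were higher, 5 were lower and 11 did not pass (7 and 7 adjusted over the list alone). Altogether 3549 genes were called, 1950 higher and 1599 lower in the libraries labelled sh-PHLPP1, and the authors' table called 2449, of which 2346 were shared with the same sign. Scaling by library size alone raised the median log2 fold change of all genes by 0.12 and put 72.5% of the called genes up, against 54.9% with TMM. The count was 6372 without sh-PHLPP1 replicate 1, 1515 and 1566 without its replicates 2 and 3, 2247 without untreated sh-Luc replicate 2, and 733 with only these 6 libraries, when Fasn and Acaca were no longer called.

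After OxLDL, inflammatory genes were far higher in the libraries labelled sh-PHLPP1 than in sh-Luc, while genes of the cell cycle and of lipid synthesis were lower. The inflammatory call held with an estimated correlation (adjusted p = 0.0149), but the calls of the cell cycle (adjusted p = 0.490), cholesterol synthesis (0.522) and fatty acid synthesis (0.522) were lost. Lcn2, the iron-binding lipocalin, was 77.8-fold higher (19.2 ± 1.16 against 1493 ± 282 CPM, SD, n = 3; 6.28 ± 0.17, SE, adjusted p = 4.55e-10). The cytokine genes Il6 (6.60 ± 0.25), Ccl5 (6.30 ± 0.18), Csf2 (6.30 ± 0.42), Lif (6.03 ± 0.37) and Il23a (5.95 ± 0.39) were higher, as were Marcks (6.68 ± 0.25) and the acute phase gene Saa3 (5.99 ± 0.29). Plxna4 (-6.67 ± 0.50) and Ctsk (-6.35 ± 0.58) were lower, as before OxLDL, and so were C1qtnf6 (-5.16 ± 0.32), the inhibitory receptor Lair1 (-4.58 ± 0.28) and the mitotic kinesin Kif20a (-4.55 ± 0.65). Phlpp1 was lower in these libraries than in sh-Luc.

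Of the inflammatory list, 25 of 26 members were higher, 0 were lower and 1 did not pass, with 25 and 0 adjusted over the list alone, and the list was higher (camera adjusted p = 8.71e-25 and adjusted p = 0.0149 with an estimated correlation). Il1b was higher by 5.07 ± 0.27. The mean log2 CPM of the list was 4.60, 4.98 and 4.89 in sh-Luc OxLDL and 7.83, 7.93 and 8.18 in the OxLDL libraries labelled sh-PHLPP1. Interferon response genes were higher (camera adjusted p = 0.000113 and adjusted p = 0.574 with an estimated correlation), with Ifit1 (3.27 ± 0.20), Rsad2 (2.98 ± 0.20) and Oasl1 (2.58 ± 0.16). 17 of 32 interferon response genes were higher, 4 were lower and 11 did not pass (17 and 4 adjusted over the list alone). Cell cycle genes were lower (camera adjusted p = 1.04e-15 and adjusted p = 0.490 with an estimated correlation), including the replication genes Cdc6 (-3.07 ± 0.27) and Mcm6 (-3.70 ± 0.37). 0 of 30 cell cycle genes were higher, 29 were lower and 1 did not pass (0 and 29 adjusted over the list alone). Their mean log2 CPM was 6.81, 6.75 and 6.83 in sh-Luc and 4.11, 4.34 and 4.21 in the libraries labelled sh-PHLPP1. Macrophage identity (camera adjusted p = 0.0920) and lysosome and autophagy (camera adjusted p = 0.0584) were not called as lists. 11 of 19 macrophage identity genes were higher, 3 were lower and 5 did not pass (12 and 3 adjusted over the list alone). 13 of 26 lysosome and autophagy genes were higher, 4 were lower and 9 did not pass (13 and 4 adjusted over the list alone). Both passed without sh-PHLPP1 OxLDL replicate 1 (adjusted p = 0.0475 each), and the lysosome list also without sh-Luc OxLDL replicate 2 (0.0330). With no filter both passed, and macrophage identity passed without both libraries that stand apart (0.0415). Fcgr1, an Fc receptor, was higher (2.43 ± 0.47), and Lyz2, lysozyme, was lower (-0.65 ± 0.11).

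Cholesterol synthesis genes were lower after OxLDL in the libraries labelled sh-PHLPP1 (camera adjusted p = 2.98e-06 and adjusted p = 0.522 with an estimated correlation), with Hmgcs1 at -1.05 ± 0.12. 0 of 24 cholesterol synthesis genes were higher, 18 were lower and 6 did not pass (0 and 18 adjusted over the list alone). Fatty acid and triglyceride synthesis was lower (camera adjusted p = 0.00430 and adjusted p = 0.522 with an estimated correlation). 3 of 19 fatty acid and triglyceride synthesis genes were higher, 13 were lower and 3 did not pass (3 and 13 adjusted over the list alone). Fasn was 7.49-fold lower (57.2 ± 9.52 against 428 ± 39.0 CPM; -2.90 ± 0.31, adjusted p = 1.96e-05), with Elovl5 (-1.49 ± 0.16), Elovl6 (-1.44 ± 0.14) and Acaca (-0.92 ± 0.15). Cd36 was not called here (419.6 ± 38.6 against 293 ± 19.7 CPM; -0.52, adjusted p = 0.0851), nor with DESeq2. It was called lower in the authors' table (-0.51, adjusted p = 8.10e-06), without both libraries that stand apart (-0.54, adjusted p = 0.000199), with only the 6 libraries compared, with no filter and with library size alone. The uptake list went both ways (median -0.24, while camera ranked it upward; camera adjusted p = 0.686), with Cxcl16 (3.12 ± 0.13) and Msr1 (0.95 ± 0.15) higher and Scarb1 (-1.10 ± 0.14) lower. 3 of 16 uptake genes were higher, 3 were lower and 10 did not pass (2 and 3 adjusted over the list alone). Genes of AMPK, AKT and PHLPP signalling were lower (camera adjusted p = 0.00387 and adjusted p = 0.406 with an estimated correlation), including Akt1 (-1.27 ± 0.12), Camkk2, a kinase upstream of AMPK (-0.91 ± 0.09), and Fkbp5 (-1.23 ± 0.13). 2 of 24 AMPK, AKT and PHLPP signalling genes were higher, 15 were lower and 7 did not pass (2 and 15 adjusted over the list alone). Glycolysis (camera adjusted p = 0.00430 and adjusted p = 0.406 with an estimated correlation) and NRF2 genes (camera adjusted p = 0.00430 and adjusted p = 0.522 with an estimated correlation) were lower as lists, with Pfkl (-2.52 ± 0.15), Tpi1 (-1.31 ± 0.12), Gsr (-1.49 ± 0.12) and G6pdx (-1.15 ± 0.10) lower and Sqstm1 higher (2.52 ± 0.20). 0 of 18 glycolysis genes were higher, 8 were lower and 10 did not pass (0 and 8 adjusted over the list alone). 2 of 25 NRF2 and oxidative stress genes were higher, 15 were lower and 8 did not pass (2 and 15 adjusted over the list alone).

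In this comparison 7240 genes were called, 3621 higher and 3619 lower in the OxLDL libraries labelled sh-PHLPP1, and 2874 had a log2 fold change of at least 1 in size. The authors' table called 7857, of which 6907 were shared with the same sign. Scaling by library size alone shifted the median of all genes by -0.26 and put 29.9% of called genes up, against 50.01% with TMM.

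In the line labelled sh-PHLPP1, OxLDL raised inflammatory genes, lipid uptake genes and lysosome genes, and lowered cell cycle genes. Of these list calls the inflammatory one held with an estimated correlation (adjusted p = 0.00333), and those of uptake (adjusted p = 0.235), lysosome (0.394) and the cell cycle (0.553) were lost. Phlpp1 fell in this comparison, from a level not below sh-Luc. Csf3 rose from 4.49 ± 0.751 to 6276 ± 1223 CPM (10.45 ± 0.41, SE, adjusted p = 3.58e-09), Lcn2 by 9.67 ± 0.21, Il6 by 9.13 ± 0.31, Marcks by 10.01 ± 0.33, and Serpinb2, the plasminogen activator inhibitor 2, by 9.14 ± 0.36. Cxcl3 had 819 counts against 1 over the 3 libraries each, a ratio of 1397 (95% counting interval 250.1 to 55260), and Ccl7 had 1071 against 2 (914, 252 to 7554). Dmpk (-4.25 ± 0.29), Kbtbd11 (-4.19 ± 0.17) and Htr1b (-3.71 ± 0.30) fell.

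Of the inflammatory genes, 25 of 26 members rose, 0 fell and 1 did not pass, with 25 and 0 adjusted over the list alone, and the list rose (camera adjusted p = 8.14e-52 and adjusted p = 0.00333 with an estimated correlation). Nos2 rose by 6.29 ± 0.19 and Ccl5 by 7.18 ± 0.19. Uptake genes rose (camera adjusted p = 0.000149 and adjusted p = 0.235 with an estimated correlation), with Fabp4 at 7.12 ± 0.35 and Msr1, the scavenger receptor A, at 2.21 ± 0.15. 9 of 16 uptake genes rose, 2 fell and 5 did not pass (9 and 2 adjusted over the list alone). Cd36 rose 13.6-fold (21.5 ± 4.48 to 293 ± 19.7 CPM; 3.77 ± 0.27, adjusted p = 4.33e-07). Lipid droplet genes rose (camera adjusted p = 0.00268 and adjusted p = 0.235 with an estimated correlation), including Hilpda (4.83 ± 0.21) and Plin2 (2.79 ± 0.15), a list call lost with no filter. 7 of 11 lipid droplet genes rose, 1 fell and 3 did not pass (7 and 1 adjusted over the list alone). Lysosome and autophagy genes rose (camera adjusted p = 2.38e-05 and adjusted p = 0.394 with an estimated correlation), including Sqstm1 (2.90 ± 0.20) and Ctsl (2.13 ± 0.16), and NRF2 genes rose (camera adjusted p = 0.00254 and adjusted p = 0.498 with an estimated correlation), including Blvrb (2.39 ± 0.15) and Fth1, the ferritin heavy chain (2.39 ± 0.16). 19 of 26 lysosome and autophagy genes rose, 2 fell and 5 did not pass (20 and 2 adjusted over the list alone). 12 of 25 NRF2 and oxidative stress genes rose, 6 fell and 7 did not pass (13 and 6 adjusted over the list alone). Fasn fell (-2.38 ± 0.31, adjusted p = 5.22e-05), as did Acaca (-0.81 ± 0.15) and Elovl5 (-1.07 ± 0.16), while the list of fatty acid and triglyceride synthesis was not called (camera adjusted p = 0.115), but passed as lower without both libraries that stand apart (-0.51, adjusted p = 0.0491) or with no filter. 4 of 19 fatty acid and triglyceride synthesis genes rose, 12 fell and 3 did not pass (4 and 14 adjusted over the list alone). Srebf1 fell (-1.004 ± 0.39, adjusted p = 0.0445), but its fall was -0.20 and not called without sh-PHLPP1 untreated replicate 1, and it was not called without any 1 of the OxLDL libraries of this line (-1.05 to -0.96).

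Cell cycle genes fell with OxLDL in the line labelled sh-PHLPP1 (camera adjusted p = 5.19e-07 and adjusted p = 0.553 with an estimated correlation), with Mcm6 at -3.19 ± 0.36, Cdc6 at -2.22 ± 0.27 and Ccnb2, cyclin B2, at -2.46 ± 0.32. 0 of 30 cell cycle genes rose, 28 fell and 2 did not pass (0 and 28 adjusted over the list alone). The untreated replicate 1 of this line stood highest in the list, at 7.07, 5.50 and 5.47 for replicates 1, 2 and 3. AMPK, AKT and PHLPP signalling fell (camera adjusted p = 0.00143 and adjusted p = 0.235 with an estimated correlation), with Camkk2 (-0.97 ± 0.09) and Stk4 (-0.999 ± 0.11) lower and Nr4a1 higher (1.94 ± 0.21). 1 of 24 AMPK, AKT and PHLPP signalling genes rose, 15 fell and 8 did not pass (1 and 15 adjusted over the list alone). Cholesterol synthesis was not called as a list (camera adjusted p = 0.0558), but passed without untreated replicate 2 (adjusted p = 0.00899) or 3 (0.00733) of this line or with no filter, and Idi1 fell (-1.995 ± 0.31). 1 of 24 cholesterol synthesis genes rose, 9 fell and 14 did not pass (1 and 8 adjusted over the list alone). Fatty acid oxidation and PPAR targets (camera adjusted p = 0.0540) passed without untreated replicate 1 (adjusted p = 0.0185) or without both libraries that stand apart (0.0179), with no filter or with library size alone, and Angptl4 fell (-2.67 ± 0.25). 2 of 18 fatty acid oxidation and PPAR target genes rose, 10 fell and 6 did not pass (2 and 10 adjusted over the list alone). The interferon list was not called (camera adjusted p = 0.105; median -0.70), but passed as lower without both libraries that stand apart (-0.79, adjusted p = 0.00640) or with no filter, while Rsad2 (3.08 ± 0.20) and Oasl1 (2.79 ± 0.16) rose. 6 of 32 interferon response genes rose, 16 fell and 10 did not pass (6 and 16 adjusted over the list alone). For p53 targets and apoptosis (camera adjusted p = 0.211) the median was -0.05 and the mean 0.46, with Fas, a death receptor, higher (5.45 ± 0.31). 6 of 19 p53 target and apoptosis genes rose, 1 fell and 12 did not pass (6 and 1 adjusted over the list alone). Altogether 7169 genes were called, 3441 up and 3728 down. Library size alone shifted the median of all genes by -0.43 and put 19.8% of called genes up, against 48.0% with TMM.

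**Figure D3:**
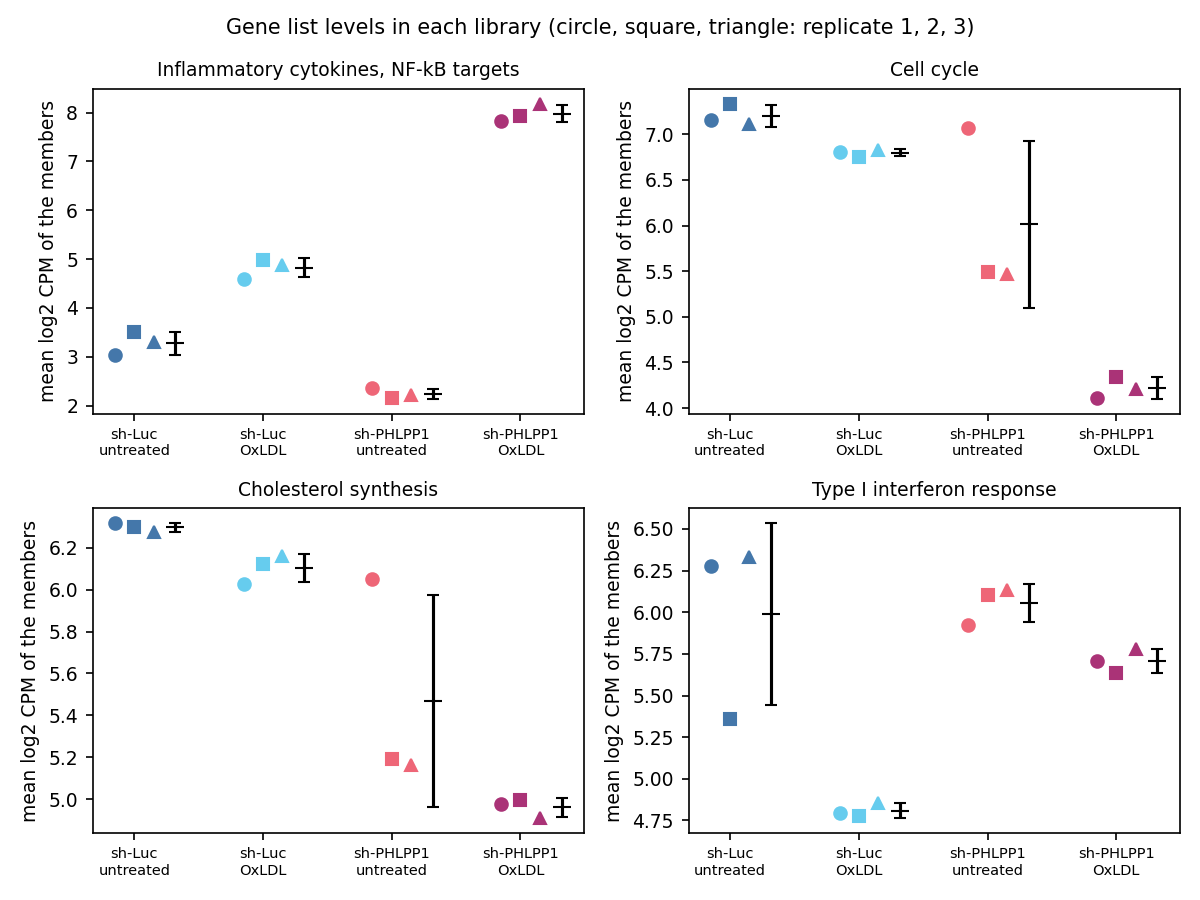
Mean log2 CPM of the members of 4 gene lists (vertical axes) in each library by group, with circle, square and triangle for replicates 1, 2 and 3, and the mean with its SD in black. Inflammatory genes reach 7.83, 7.93 and 8.18 in the OxLDL libraries labelled sh-PHLPP1, and cell cycle genes stand at 7.07, 5.50 and 5.47 in untreated replicates 1, 2 and 3 of that label.

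The test of the difference between the OxLDL responses called 3231 genes, 1451 with a higher and 1780 with a lower change in the line labelled sh-PHLPP1, whose untreated libraries were not lower in Phlpp1. Lif (8.15 ± 0.52, SE, adjusted p = 1.43e-06), Serpinb2 (8.04 ± 0.49), Marcks (7.95 ± 0.71), Lcn2 (7.27 ± 0.24) and Il1b (7.15 ± 0.50) had the highest values of this difference on the log2 scale. The inflammatory list rose more in that line (camera adjusted p = 1.23e-48 and adjusted p = 0.00156 with an estimated correlation). 24 of 26 inflammatory genes were higher, 0 were lower and 2 did not pass (24 and 0 adjusted over the list alone). Cd36 also had a higher value of this difference (2.60 ± 0.35, adjusted p = 0.000365) and started lower in that line. Untreated, Cd36 stood at 26.4, 20.6 and 17.6 CPM there, against 133, 282 and 146 CPM in sh-Luc. After OxLDL it stood at 315, 285 and 278 CPM, against 376, 432 and 450 CPM. The uptake list had a higher value too (camera adjusted p = 3.84e-05 and adjusted p = 0.311 with an estimated correlation). Its median between the lines was -0.55 untreated and -0.24 after OxLDL. The interferon list also had a higher value (camera adjusted p = 1.73e-06 and adjusted p = 0.591 with an estimated correlation). 7 of 16 uptake genes were higher, 1 was lower and 8 did not pass (7 and 1 adjusted over the list alone). 13 of 32 interferon response genes were higher, 1 was lower and 18 did not pass (13 and 1 adjusted over the list alone). The interferon list had a negative median for OxLDL in both lines, -1.18 in sh-Luc and -0.70 in the line labelled sh-PHLPP1. By median its higher value thus marks a smaller fall, with 6 members up and 16 down in the latter line. Untreated sh-Luc replicate 2 stood lower than its group in the interferon list. The response of the cell cycle list was lower (camera adjusted p = 1.19e-06 and adjusted p = 0.591 with an estimated correlation), with a median of -1.72 that came to -0.81 without sh-PHLPP1 untreated replicate 1, the library near the sh-Luc level of this list (7.07, 5.50 and 5.47 in replicates 1, 2 and 3). Examples were Cenpf, a kinetochore protein (-3.19 ± 0.63), and Ccne2, cyclin E2 (-3.11 ± 0.42). 0 of 30 cell cycle genes were higher, 17 were lower and 13 did not pass (0 and 24 adjusted over the list alone). It was also lower for Fasn (-1.60 ± 0.42, adjusted p = 0.0170; -1.05 without sh-PHLPP1 untreated replicate 1) and Phlpp1 (-0.77 ± 0.19, adjusted p = 0.0133). Acaca was not called (-0.24, adjusted p = 0.417). The AMPK, AKT and PHLPP list (camera adjusted p = 0.00139 and adjusted p = 0.344 with an estimated correlation) and fatty acid oxidation and PPAR targets (camera adjusted p = 0.0158 and adjusted p = 0.349 with an estimated correlation) had lower responses. 1 of 24 AMPK, AKT and PHLPP signalling genes was higher, 13 were lower and 10 did not pass (1 and 13 adjusted over the list alone). 1 of 18 fatty acid oxidation and PPAR target genes was higher, 5 were lower and 12 did not pass (1 and 5 adjusted over the list alone). Lysosome genes (camera adjusted p = 0.0159 and adjusted p = 0.591 with an estimated correlation) had a higher one, a list call lost without untreated sh-Luc replicate 2 (adjusted p = 0.146) or both libraries that stand apart (0.203). 7 of 26 lysosome and autophagy genes were higher, 1 was lower and 18 did not pass (7 and 1 adjusted over the list alone). Library size alone shifted the median of all genes by -0.38 and put 11.9% of called genes up, against 44.9% with TMM. The count was 2114 without sh-Luc OxLDL replicate 3 and 5319 without both libraries that stand apart.

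Among the 1242 genes changed by OxLDL in sh-Luc cells, 197 (15.9%) moved the opposite way between the lines after OxLDL. Another 625 (50.3%) moved the same way. The 95% binomial interval of the former share was 13.9 to 18.0%. It takes the genes as independent and does not measure the spread between libraries. With 1 library left out the share could fall outside it, as given below. Of the 837 genes that rose with OxLDL, 428 were still higher in the OxLDL libraries labelled sh-PHLPP1, against 231.0 for independent lists, and 136 were lower, against 230.9. Of the 405 that fell, 197 were still lower, against 111.7, and 61 were higher, against 111.8. These comparisons share the sh-Luc OxLDL libraries, which alone gave a covariance of the fold changes across genes of -0.03 in simulation, against 0.16 observed. That simulation drew each gene independently, without shifts shared by many genes of 1 library. It called 2014 to 2209 genes for OxLDL in sh-Luc, against 1242 observed, so it does not match the data closely. With each sh-Luc OxLDL library used in 1 comparison only, 10.2 to 18.8% of the called genes moved the opposite way and 33.2 to 55.6% the same way. The OxLDL responses of the lines, which share no library, had 656 genes up in both (219.5 for independent lists), 327 down in both (115.1), and 18 and 19 in opposite directions. The differences between the lines without and with OxLDL shared 1061 genes that were higher (538) and 1023 that were lower (441) in the libraries labelled sh-PHLPP1, with 115 and 124 in opposite directions.

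In CPM of library totals, without TMM factors, the highest levels of markers of other cell types in any library were 27.8 for Ighm, an immunoglobulin gene, and 19.6 for Lck among lymphocyte markers, 5.06 for Itgax among dendritic cell markers, and 2.07 for Col1a2 among fibroblast and epithelial markers. Only 2 lymphocyte and 2 dendritic cell markers could be tested, so these lists were not given to camera. Ighm (3.20 ± 0.60, adjusted p = 0.00361), Lck (1.06 ± 0.25) and Zbtb46 (1.85 ± 0.41) were higher in the untreated libraries labelled sh-PHLPP1 than in untreated sh-Luc, and Ighm fell with OxLDL in that line (-2.88 ± 0.61). Fibroblast and epithelial markers were not called as a list in any comparison, but all 3 that could be tested rose with OxLDL in the line labelled sh-PHLPP1 by edgeR and by DESeq2: Col1a1 (1.71 ± 0.60), Col3a1 (1.32 ± 0.50) and Col1a2 (1.06 ± 0.42; camera adjusted p = 0.348). Leaving out any 1 of the 6 libraries compared ended at least 1 of these calls (0.74 to 1.75). The mitochondrially encoded mRNAs had no counts in any library.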

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

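The swap test, the interval test and the starting-level test, the test for OxLDL-treated cells in untreated sh-Luc replicate 2, scaling by library size alone, the fits without both libraries that stand apart, the drawn set of interaction splits and the set that kept the OxLDL libraries by line were chosen only after the result was seen. In the test for sh-Luc cells in sh-PHLPP1 untreated replicate 1, the smallest number of genes allowed was lowered after the value was seen.

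The results in this part were picked out because the OxLDL response differed between the lines by a test of the difference itself (log2 scale, the line labelled sh-PHLPP1 minus sh-Luc), for 3231 genes in all. Among named genes the difference was 8.15 for Lif, 8.04 for Serpinb2, 7.95 for Marcks, 7.27 for Lcn2, 7.15 for Il1b and 2.60 for Cd36. It was -3.39 for Pirb, -3.19 for Cenpf, -3.11 for Ccne2 and -0.77 for Phlpp1. Ankle1 stood at -3.53, with -2.05 without sh-PHLPP1 untreated replicate 1 and no call without sh-PHLPP1 OxLDL replicate 3 (-3.51). Kif20a stood at -3.29 and Fasn at -1.60, with -1.94 and -1.05 without sh-PHLPP1 untreated replicate 1. Phlpp2 stood at -0.86, a call lost without untreated sh-Luc replicate 1 (-0.87) or 3 (-0.80), sh-Luc OxLDL replicate 1 (-0.78) or 2 (-0.90), or sh-PHLPP1 untreated replicate 2 (-0.82). The list medians were 4.52 for inflammatory genes, -0.34 for fatty acid oxidation and PPAR targets, and -0.64 for AMPK, AKT and PHLPP signalling. For the cell cycle it was -1.72, with -0.81 without sh-PHLPP1 untreated replicate 1. The interferon response had 0.62, with 0.41, 0.99 and 0.34 without untreated sh-Luc replicates 1, 2 and 3. Uptake had 0.10, with 0.023 without sh-Luc OxLDL replicate 1, 0.85 without sh-PHLPP1 untreated replicate 1, and 0.16 to 0.26 without any other library apart from sh-Luc OxLDL replicate 3 and sh-PHLPP1 OxLDL replicate 1. The lysosome list had a median of 0.37, and its call was lost without untreated sh-Luc replicate 2 (0.19).

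Other splits of the libraries were counted for each edgeR count. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each comparison of 2 groups 1 split, the real one, gave as many genes. The real and the highest other counts were 1242 and 0 for OxLDL in sh-Luc, 3549 and 14 between the untreated lines, 7240 and 0 between the lines after OxLDL, and 7169 and 0 for OxLDL in the line labelled sh-PHLPP1. The other splits mix the 2 groups, which puts the group difference into the spread. Their low counts therefore do not show what chance alone would give. For the interaction a first set of 100 splits, with the direction of the lines held fixed, gave 2 with at least the real 3231 genes and 6447 as the highest other. After that was seen it was replaced by 100 splits drawn from all 200, of which 4 were as large, with 6653 as the highest other. The share lay under 0.05 in both sets. Splits that mixed the OxLDL libraries put the line difference after OxLDL into the spread, which lowers their counts. The share under 0.05 is therefore no evidence against chance. Every split as large kept the OxLDL libraries by line, and all 20 splits that do so were then run. Of these 5 were as large, 7365 with all untreated labels exchanged, and the other 15 gave 2100 to 3159 genes, while splits of both earlier sets that mixed the OxLDL libraries gave at most 22. Counts from 2100 to 7365 thus came with all 20 labellings of the untreated libraries that kept the OxLDL libraries by line. Each of these labellings still holds the line difference after OxLDL, so they cannot show what chance would give for the interaction. With all untreated labels exchanged, the value tested is the sum of the line differences without and with OxLDL. The 3 remaining splits above the real count had replicates 2 and 3 of the untreated sh-PHLPP1 libraries exchanged with sh-Luc libraries.

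The untreated libraries labelled sh-PHLPP1 did not have less Phlpp1 than untreated sh-Luc. An exchange of the untreated libraries between the lines was argued against, because 83.8% of the 798 genes with large line differences after OxLDL had the same sign in the untreated comparison (87.7% of 667 in a first form of the test, without genes called for OxLDL in sh-Luc). Too few reads were argued against as well, since the 95% interval of the untreated log2 fold change began at -0.089, above -1. Scaling did not account for it, with a lowest log2 fold change of 0.16 over the scalings. A hairpin that lowered protein more than transcript, or that had lost its effect in those cultures, was not tested and stays open.

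The inflammatory genes had a median difference in OxLDL response of 4.52 between the lines. It was 4.14 under the scaling that lowered it most, and 4.10 after a trend on GC content and transcript length was removed. Scaling moves all genes nearly alike, by a median of -0.38 with library size alone, and the trend held 7.26% of the variance. Neither could have removed most of 4.52, so these values show only that the scalings tried and this trend account for little of it. Without both libraries that stand apart the median difference was 4.14, so those libraries as the whole cause were argued against. A lower starting level alone was also argued against, since the list lay 2.91 higher between the lines after OxLDL. Its median between the untreated lines was -1.15, so a lower start made up part of the difference. The labels give 1 stable line per shRNA, so a difference between the lines other than the hairpin cannot be told apart from an effect of the hairpin, and the untreated Phlpp1 levels leave the latter uncertain. An effect of PHLPP1 on the inflammatory response may thus be no more than a candidate explanation.

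Replicate 1 of the untreated sh-PHLPP1 libraries and replicate 2 of the untreated sh-Luc libraries stood apart from their groups. For the former, sh-Luc cells in the culture were argued against: 5 genes nearly off in replicates 2 and 3 had a median share of 0.00703 of their sh-Luc level (quartiles 0.00580 and 0.0240), against an overall shift of 0.706 towards sh-Luc. That test rests on 5 genes. For the latter, OxLDL-treated cells or carry-over may have played a part, as 61 genes raised by OxLDL had a median share of 0.104 (quartiles 0.0107 and 0.285) against an overall shift of 0.313, which leaves this open. No biological explanation was tested for either library.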

How the results depend on the processing

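Scaling by library size alone and leaving out both libraries that stand apart were chosen only after the data were seen, and the other alternatives were set before. Depth may limit what was called for genes near the filter, which was not tested. Simulated changes were recovered in 14.9 to 20.9% of genes at 1.5-fold and 68.7 to 76.1% at 2-fold between 2 groups. In the interaction the shares were 1.49 and 28.4%, so a gene not called is not shown to be unchanged. A log2 fold change of at least 1 left 491, 1181, 2874, 2873 and 1501 genes for OxLDL in sh-Luc, the untreated lines, the lines after OxLDL, OxLDL in the line labelled sh-PHLPP1 and the interaction, by its own construction. An estimated correlation between genes left 2, 0, 1, 1 and 1 lists called by camera in the same order, from 10, 8, 8, 7 and 7. The preset was 0.01, while for OxLDL in sh-Luc the estimates ran from 0.0114 (alternative activation and foam cells) to 0.870 (cell cycle). Interferon response genes had 0.626. Camera widens the variance of a list as this correlation rises, so p-values at the preset are too small where the estimate is far higher. The counts for OxLDL in sh-Luc were 1948 with DESeq2 and 2944 with only the groups compared, and that setting gave 733 between the untreated lines. Of 308 values for named genes, fitting only the groups compared ended 29 calls and added 13. That setting was not run for the interaction, which needs all 12 libraries. Without both libraries that stand apart, 3528 genes were called for OxLDL in sh-Luc, 6267 between the untreated lines and 5319 in the interaction, 12 lists for OxLDL in the line labelled sh-PHLPP1 (also 12 with no filter), and the share moved the opposite way was 21.1%. That share was 18.8% with library size alone; the causes were not tested.

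With 1 library left out the counts ran from 564 to 1342 for OxLDL in sh-Luc, from 1515 to 6372 between the untreated lines, from 6114 to 6670 between the lines after OxLDL, from 6151 to 7535 for OxLDL in the line labelled sh-PHLPP1 and from 2114 to 4496 for the interaction. The share moved the opposite way ran from 13.8 to 23.0%. Lists called ran from 8 to 10, 6 to 8, 8 to 10, 7 to 8 and 7 to 8 in the order above. The log2 fold change of Phlpp1 kept its direction and its side of the threshold in every setting run. The causes were not tested.

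For lists a turn here means the direction that camera ranked, and the value beside it is the list's median, which often kept its sign. A replicate block, for numbers that do not pair the libraries, ended 7 and added 4 of 384 gene calls, added 4 list calls, and turned the camera direction of 3 lists that were not called: cholesterol efflux and LXR targets for OxLDL in sh-Luc (0.10) and in the line labelled sh-PHLPP1 (0.057), and glycolysis there (0.00083). No called gene or list turned its direction under any setting, and the causes of the turns listed here were not tested. Of 384 values for genes, the setting without both libraries left 358, DESeq2 369 and no filter 367 with the same direction and on the same side of the threshold. DESeq2 size factors turned Phlpp2 for OxLDL in sh-Luc (-0.0022), as did the DESeq2 test (-0.0015) and library size alone (-0.017). No filter turned Prkaa1 in the interaction (-0.057) and the uptake list between the lines after OxLDL (-0.31). Library size alone turned Prkaa1 between the untreated lines (0.072) and in the interaction (-0.38), Lck for OxLDL in the line labelled sh-PHLPP1 (-0.15) and in the interaction (-0.26), Col1a2 in the interaction (-0.051) and the AMPK, AKT and PHLPP list between the untreated lines (0.091). Without both libraries Lck for OxLDL in sh-Luc (-0.10), Col1a2 between the untreated lines (-0.16), Itgax for OxLDL in the line labelled sh-PHLPP1 (0.94) and Prkaa1 in the interaction (-0.016) turned. So did the lists of fatty acid oxidation for OxLDL in sh-Luc (0.0031), of endoplasmic reticulum stress (-0.18) and lysosome (0.11) between the untreated lines, and of cholesterol synthesis (-0.072) and LXR targets (0.034) in the interaction.

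With 1 library left out, uncalled genes that turned ranged from -0.068 to 0.11 (Phlpp2) and -0.10 to 0.36 (Lck) for OxLDL in sh-Luc, from -2.07 to 0.0072 (Itgax) and -0.70 to 0.11 (Col3a1) between the untreated lines, and from -0.71 to 0.94 (Itgax) for OxLDL in the line labelled sh-PHLPP1. In the interaction they ranged from -0.037 to 0.045 (Prkaa1), -0.10 to 0.36 (Lck), -0.20 to 0.59 (Col1a2), -1.74 to 0.34 (Itgax) and -1.03 to 0.074 (Srebf1). For lists whose camera direction turned, medians for OxLDL in sh-Luc ranged from -0.15 to 0.29 (LXR targets), 0.17 to 0.81 (osteoclast), 0.0011 to 0.56 (fibroblast) and -0.067 to 0.036 (fatty acid oxidation). Between the untreated lines they ranged from -0.22 to 0.11 (interferon), -0.14 to 0.17 (lysosome), -0.24 to 0.21 (LXR targets), -0.70 to 0.11 (fibroblast), -0.088 to 0.55 (endoplasmic reticulum stress), -0.067 to -0.017 (AMPK, AKT and PHLPP) and -0.0044 to 0.16 (p53). After OxLDL, LXR targets ranged from 0.015 to 0.10 between the lines. For OxLDL in the line labelled sh-PHLPP1 the ranges were -0.029 to 0.22 (LXR targets) and -0.0068 to 0.086 (glycolysis). In the interaction they were -0.14 to 0.21 (LXR targets), -0.47 to 0.20 (osteoclast), -0.021 to 0.27 (endoplasmic reticulum stress) and -0.47 to 0.017 (cholesterol synthesis).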

Other observations

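Apart from the fit without both libraries that stand apart, which was chosen only after the result was seen, the test in this part was set before, and the gene groups come from the lists fixed beforehand. Between the lines after OxLDL, where the libraries labelled sh-PHLPP1 had less Phlpp1, members of the foam cell and osteoclast lists were called in both directions. Of all genes tested, 55.2% were called in this comparison. Clec10a, a lectin receptor (2.71 ± 0.41), and Klf4 (1.46 ± 0.22) were higher and Trem2, a lipid-sensing receptor (-1.72 ± 0.22), was lower in the libraries labelled sh-PHLPP1. The list of alternative activation and foam cell genes was not called (camera adjusted p = 0.307). 5 of 13 alternative activation and foam cell genes were higher, 2 were lower and 6 did not pass (5 and 2 adjusted over the list alone). Among osteoclast markers Siglec15 (-3.67 ± 0.55) was lower and Mmp9, a matrix protease, higher (2.52 ± 0.22), and the list was not called (camera adjusted p = 0.0994) but passed when both libraries that stand apart were left out (adjusted p = 0.00613), a fit chosen after the data were seen, or with no filter. 1 of 14 osteoclast markers was higher, 8 were lower and 5 did not pass (1 and 8 adjusted over the list alone). Angptl4, an inhibitor of lipoprotein lipase (-2.41 ± 0.25), and Cpt1a, the carnitine palmitoyltransferase of mitochondrial fatty acid import (-1.32 ± 0.18), were lower in a fatty acid oxidation list that was not called (camera adjusted p = 0.289). Lipid droplet genes Hilpda (1.47 ± 0.18) and Dgat2 (2.10 ± 0.27) were higher (camera adjusted p = 0.307 for the list).

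In the line labelled sh-PHLPP1, OxLDL changed macrophage genes in both directions, with Phlpp1 lower after OxLDL. Of all genes tested, 54.6% were called here. The transcription factor gene Cebpb (2.03 ± 0.16) and the integrin gene Itgam (1.91 ± 0.22) rose and Cebpa fell (-1.53 ± 0.15), while the list was not called (camera adjusted p = 0.115), except with no filter. 10 of 19 macrophage identity genes rose, 4 fell and 5 did not pass (11 and 4 adjusted over the list alone). Spp1 rose by 2.04 ± 0.25 and Trem2 fell (-1.44 ± 0.22) in the alternative activation and foam cell list, which was not called (camera adjusted p = 0.0842). That list passed without both libraries that stand apart (adjusted p = 0.0406). 7 of 13 alternative activation and foam cell genes rose, 2 fell and 4 did not pass (8 and 2 adjusted over the list alone). Mmp9 rose by 5.32 ± 0.26 and Nfatc1, a transcription factor of osteoclast formation, fell (-1.48 ± 0.34). Among efflux genes Abcg1, a sterol transporter (-2.15 ± 0.34), and Pltp (-1.32 ± 0.16) fell in a list that was not called (camera adjusted p = 0.979). 7 of 17 efflux and LXR target genes rose, 5 fell and 5 did not pass (7 and 5 adjusted over the list alone). Soat1, of the lipid droplet list, which esterifies cholesterol, rose (1.17 ± 0.21). Glycolysis genes went both ways, with the glucose transporter gene Slc2a1 (1.89 ± 0.23) and Hk3 (1.34 ± 0.15) up and Pfkl down (-1.94 ± 0.15; camera adjusted p = 0.979). 5 of 18 glycolysis genes rose, 5 fell and 8 did not pass (5 and 5 adjusted over the list alone).

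A hypothesis was that genes raised by OxLDL in sh-Luc cells may start lower in untreated cells labelled sh-PHLPP1. The result did not show this, but it does not decide either. The 837 genes raised by OxLDL had a median log2 fold change of 0.10 between the untreated lines, and the covariance of both effects across genes was 0.0852. The shared untreated sh-Luc libraries alone raised both in simulation, to a median of 0.0749 (0.0646 to 0.0883) and a covariance of 0.0364 (0.0317 to 0.0400), both below the observed values. That simulation drew each gene independently, without shifts shared by many genes of 1 library, such as untreated sh-Luc replicate 2. It called 2014 to 2209 genes for OxLDL in sh-Luc, against 1242 observed, so its ranges may be too narrow. The Pearson correlation of both effects went the other way, at 0.196 observed against 0.201 to 0.260 in simulation. The hypothesis stays open.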
